A study of Drosophila melanogaster with 12 samples.

How the data were processed

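Ovary RNA was measured by RNA-seq in 12 libraries of Drosophila melanogaster. Per the labels' protocols, flies were fed yeast and kept at 25°C, total RNA was taken from their ovaries with Trizol, and libraries were made with not-so-random primers, selected by size and sequenced on an Illumina HiSeq instrument. The fly age is given without its unit. The deposited values are raw counts of reads per gene, whole numbers that the authors did not normalise, in 1 table of all 12 libraries. Per the submitters' processing notes, bcl2fastq 1.8.4, cutadapt 1.16, STAR 2.5.2a and the genome dm3 were used for all 12 libraries. The same notes name deepTools 2.5.7 and featureCounts 1.6.1 for the wild-type, knockdown and mutant libraries only. The counting tool of the 4 Panx FL10B libraries, the gene annotation and any use of strand are not given in the sources used here. Reads of near-identical copies (Hsp70, replication histones, 7SL RNA), of overlapping genes and of small RNA genes inside other genes can therefore be split or shared in ways that cannot be checked.

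Libraries were grouped by title into attp2, W1118, knockdown, mutant, and heterozygote and mutant with Panx FL10B, with 2 libraries each and no column left unused. Which wild-type stock belongs to which nxf2 group was read from the names alone, so the other stock and the mean of both were also used as control. Libraries of the Panx mutant with tethered dNxf2 are not in the table and were not analysed here.

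Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 8638 of 15446. Libraries were scaled by TMM, and robust quasi-likelihood tests were run in 1 model of all 12 libraries with 6 groups, 6 residual degrees of freedom, a median prior of 7.63 degrees of freedom and a common biological coefficient of variation of 0.102. The 6 groups share 1 estimate of the spread, since 2 groups of 2 leave few degrees of freedom. The replicates were not equally spread, however. Their chi-square per degree of freedom was 35.7 in attp2 and 16.75 in the knockdown, and 2.47 and 2.02 in the heterozygote and mutant with Panx FL10B. A shared estimate can therefore make the error of the knockdown comparison too small and that with Panx FL10B too large. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this test. CPM are the edgeR CPM of the deposited counts with the TMM factors, given as mean ± SD of 2 libraries, and log2 fold changes have a standard error from the same fit. The contrasts were knockdown minus attp2, mutant minus W1118, mutant minus heterozygote with Panx FL10B, W1118 minus attp2, and 2 differences of these effects. Overlaps of call lists were set against those of independent lists by one-sided Fisher exact tests, adjusted over 6 overlaps.

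The depth, 3811630 to 11260925 counts, puts 3 counts at 0.275 to 0.772 CPM per library. Where a group had no count of a gene, its fold change is a lower bound from 3 counts over the group. With 1 to 3 counts, the ratio of summed counts is given with its 95% counting interval. Intervals and floors cover counting error only.

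Genes are named by a rule with 4 parts. nxf2, Panx, Nxt1 and piwi were taken in every comparison. The 8 largest rises and 8 largest falls per comparison were taken among called genes whose groups do not overlap and whose higher mean is at least 10 CPM. The 2 members with the smallest p of each list with a called member were taken, and the 4 largest in each direction for the 2 differences of effects. The text gives the values of some of them and counts of the rest. Some genes outside the rule, such as wde, Su(var)3-3, sls, wupA, Cad99C and hid, were named after their values were seen. Nxt1 did not change in the 3 comparisons of nxf2 (adjusted p = 0.216, 0.668 and 0.797).

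The 24 gene lists were written from general knowledge of the ovary and the piRNA pathway. They hold piRNA transcriptional silencing factors, piRNA cluster transcription and export, piRNA biogenesis and nuage, transposons, nuclear RNA export factors, oocyte and maternal mRNA localization, early germline and meiosis, chorion and vitelline membrane, yolk, follicle cell patterning, ecdysone, DNA damage and apoptosis, heat shock, antimicrobial and immune genes, testis, muscle, fat body, midgut enzymes, hemocytes and basement membrane, reproductive tract, transgene markers, ribosomal proteins, replication histones and mitochondrially encoded genes. None of 30 transposon names is in the table, and none of the 37 mitochondrially encoded genes in it passed the filter. The 19 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Each list was tested again with an estimated correlation and with fry, which asks whether its genes move on balance one way and does not compare them with other genes. Of the calls for the 4 comparisons of groups, the eggshell list with Panx FL10B held with an estimated correlation and the others did not. Counts of list members are also given adjusted over the list alone. Every called list kept its direction under TMM, RLE, upper-quartile and no scaling, which moved the median of all genes by at most 0.07.

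Chromosome arms and nearby annotated transposons were taken from assembly BDGP6.54, Ensembl release 115, which matched 8523 of the 8638 tested genes (98.7%) by current or older symbol. It is a later build than that of the counts, so no coordinates are given.

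The comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a filter at a mean of 5 CPM, a minimum change of 2-fold, a fit of the compared groups alone, other controls, the replicate number as a block, and leaving out each library in turn. One more, without small RNA and multi-copy genes, was chosen after seeing the data. The tests were checked on simulated counts with 200 changed genes. All other genes had the same mean in every group, and each gene had 1 spread for all groups. In the data the spread of replicates differed by group (chi-square per degree of freedom 1.59 to 35.7) and more genes were called. The rates that follow therefore hold for the simulated setting only. For the knockdown design (8401 genes), 50.7% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 6.45% of calls false. The mutant design (8405 genes) recovered 38.8%, 67.2% and 92.4% with 8.33% false, the Panx FL10B design (8401 genes) 55.2%, 83.6% and 89.4% with 7.88% false, and that of the stocks (8393 genes) 46.3%, 71.6% and 86.4% with 7.48% false. A simulated list raised 2-fold among the 8638 genes was called in each of the 4 designs. In the knockdown and Panx FL10B designs 1 other list, not raised, was called too, and where nothing was changed camera called 0 of 19 lists.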

Results

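RNA from Drosophila melanogaster ovaries was sequenced in 12 libraries, which fell into 6 groups of 2. The groups were the wild-type stocks attp2 and W1118, a germline knockdown of nxf2 (dNxf2), a CRISPR mutant of nxf2, and a heterozygote and a mutant of nxf2 whose labels both name Panx FL10B and call it tethered. What FL10B stands for is not given in the sources used here. nxf2 encodes a member of the nuclear RNA export factor family, and Panx, listed as CG9754, acts with Piwi in piRNA-guided transcriptional silencing of transposons. Total counts were 11100934 and 11260925 in attp2, 9274939 and 9228876 in the knockdown, 3811630 and 6467850 in W1118, and 8817078 and 7661682 in the mutant. They were 5014910 and 6457363 in the heterozygote with Panx FL10B and 7777177 and 6757748 in the mutant with Panx FL10B. Of 15446 listed genes, 1698 had no count in any library and 8638 were tested. Across genes, Pearson's r between the 2 replicates lay between 0.984 in attp2 and 0.994 in the mutant with Panx FL10B, and genes are not independent replicates. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom from 1.59 in W1118 to 35.7 in attp2. The first principal component held 45.1% of the variance and set apart the attp2 and knockdown libraries, at -47.2 to -48.8, those of W1118 and the mutant, at -12.5 to 4.07, and those with Panx FL10B, at 37.4 to 67.2. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. No transposon was listed among the counted genes, and transposon RNA was not analysed here.

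The targeted gene was examined in every library first. In attp2, nxf2 stood at 36.1 and 49.2 normalised counts (CPM), and in the knockdown at 19.0 and 17.2, a fall of 2.35-fold (log2 fold change -1.23, SE 0.15, adjusted p = 0.000158). W1118 had 69.5 and 68.8 CPM and the mutant 29.9 and 33.6, a fall of 2.18-fold (log2 -1.12, SE 0.14, adjusted p = 0.000152). The libraries labelled heterozygote with Panx FL10B had 34.6 and 35.8 CPM and those labelled mutant with Panx FL10B 30.2 and 30.1, a log2 difference of -0.22 (SE 0.15) that did not pass (adjusted p = 0.334). The nxf2 RNA level therefore does not check which of these last libraries were mutant, and their genotype is taken from the labels. Panx was at 339.5 ± 1.12 and 295.5 ± 4.63 CPM (SD, n = 2) in the 2 Panx FL10B groups and between 39.8 ± 0.98 and 228.9 ± 4.96 CPM elsewhere. piwi was at 1299 ± 414 CPM in attp2 and 1111 ± 542 CPM in the knockdown, and between 277.9 ± 2.38 and 306.9 ± 2.84 CPM in the other 4 groups.

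**Figure D1:**
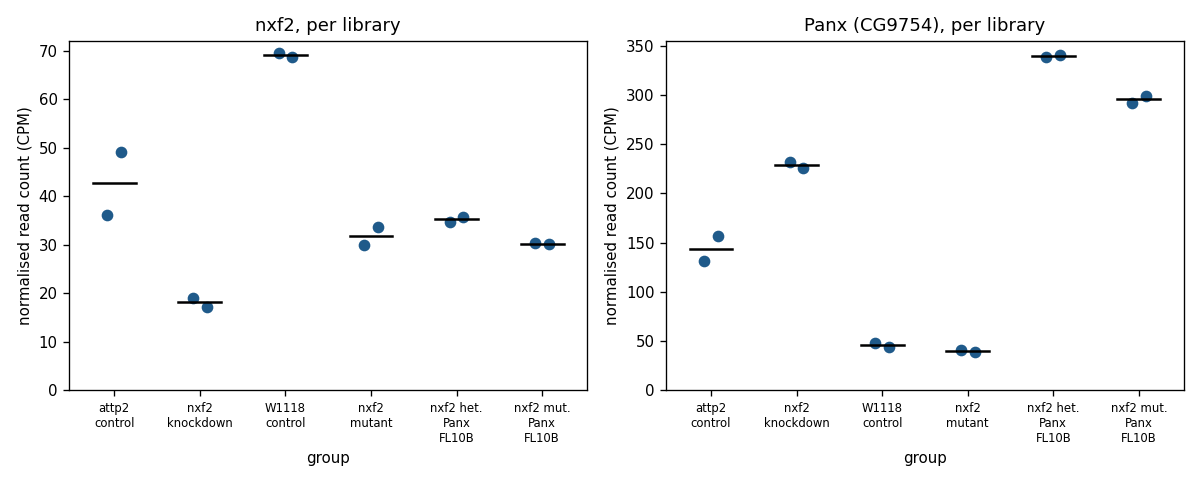
Normalised read count (CPM, linear axis from 0) of nxf2 and of Panx (CG9754) in each of the 12 libraries, by group, with a line at the mean of the 2 libraries. nxf2 fell from 42.6 to 18.1 CPM in the knockdown and from 69.1 to 31.7 CPM in the mutant, and stood at 35.2 and 30.2 CPM in the Panx FL10B groups.

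The knockdown and attp2 were compared to ask how the ovary transcriptome changed when nxf2 was reduced in the germline. Genes that attp2 hardly expressed appeared in the knockdown. CG31202, on chromosome arm 3R, rose from 0.184 ± 0.00169 to 78.5 ± 30.6 CPM (SD, n = 2), a log2 fold change of 8.61 (SE 0.41, adjusted p = 3.71e-07). Shawl, a potassium channel gene, went from 1 count in both attp2 libraries together to 28.4 ± 13.5 CPM, a ratio of 615 (95% counting interval 110 to 24300, adjusted p = 2.06e-06), and prom rose by a log2 of 6.63 to 29.1 ± 1.89 CPM. Outside the knockdown Shawl was at most at 0.404 CPM in any group, with 0.0649 CPM in the mutant. Whether the knockdown differed from attp2 in stock apart from nxf2 was not tested. Syt4, which encodes a synaptotagmin, rose by a log2 of 4.66 to 49.1 ± 5.3 CPM. The genes that fell furthest with no call lost on leaving out a library included CG43250, from 89.5 ± 73.4 to 4.79 ± 0.907 CPM, CG6910, from 28.2 ± 3.32 to 3.91 ± 0.644 CPM, and Ilp7, an insulin-like peptide gene, from 22.9 ± 13 to 2.96 ± 1.02 CPM.

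Most eggshell genes rose in the knockdown. Of 22 tested chorion and vitelline membrane genes, 16 rose and none fell (16 and 0 adjusted over the list alone), among them Vm32E from 172 ± 5.2 to 460.5 ± 19 CPM (SD, n = 2) and psd from 166.2 ± 6.03 to 423.5 ± 13.7 CPM. The list was split by gene name after the values were seen, with dec-1 and Fcp3C grouped with the vitelline membrane genes. All 9 genes of the vitelline membrane group rose, with a median log2 fold change of 1.36. Of the 12 chorion genes 6 rose, with a median of 0.60 and a range from -1.53 to 1.18. The list had an adjusted p of 2.48e-12 in camera, and adjusted p = 0.0777 with an estimated correlation. Of the yolk list, 1 of 9 rose and 1 fell (3 and 1 adjusted over the list alone), with ndl, a protease gene of the egg's dorsoventral pathway, 1.93-fold higher. Of 16 genes of ecdysone synthesis and response 5 rose (6, with 1 lower, adjusted over the list alone), including Eip74EF at a log2 of 1.28 (SE 0.23) and br at 0.63 (SE 0.10). The ecdysone list did not pass (adjusted p = 0.0634), but did with upper-quartile scaling (0.0456), unscaled (0.0365) and without knockdown replicate 1 (0.0365). Of 17 heat shock genes 7 rose and 2 fell, the same numbers adjusted over the list alone, led by the near-identical copies Hsp70Bb (log2 4.31) and Hsp70Ba (3.60), between which reads may have been split. The heat shock list did not pass (adjusted p = 0.0687), but did with upper-quartile scaling (0.0456), unscaled (0.0371) and without knockdown replicate 1 (0.000311).

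Some ribosomal protein genes and replication histones were lower in the knockdown. Of 88 ribosomal protein genes 14 fell and 0 rose, also adjusted over the list alone, and 23 fell with upper-quartile scaling (camera adjusted p = 6.76e-05, and adjusted p = 0.609 with an estimated correlation). Of 21 replication histones, copies that share reads, 5 fell and 0 rose on both adjustments (adjusted p = 1.09e-07, and adjusted p = 0.337 with an estimated correlation). Among the 21, His4:CG33891, His4:CG33893, His4:CG33895, His4:CG33897 and His4:CG33899 had equal means in every group, 9.16 CPM in attp2 and 4.31 CPM in the knockdown. Falls counted among these copies may be 1 measurement, which the list p would count more than once. The calls of His4:CG33891 and His4:CG33893 were lost with DESeq2 (adjusted p = 0.241) and in an edgeR fit of these 4 libraries alone (adjusted p = 0.0964). They were also lost when attp2 replicate 2 or either knockdown replicate was left out. Tsf1, a transferrin gene of the fat body list, fell 11.5-fold from 2.86 ± 1.07 CPM (SD, n = 2) as the 1 of its 9 members to pass. The fat body list passed at 0.0375 but not without attp2 replicate 1 (0.0916), without knockdown replicate 2 (0.0944) or unscaled (0.0789), and had an adjusted p = 0.468 with an estimated correlation. Follicle cell patterning had 3 of 17 higher, among them Fas3 at a log2 of 0.68, and passed at 0.04, with adjusted p = 0.609 with an estimated correlation. It was lost without attp2 replicate 2 (0.291) or knockdown replicate 2 (0.208).

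A few genes of the piRNA pathway changed in the knockdown, where 15.7% of all tested genes were called, and no piRNA list passed in camera. Of the 15 transcriptional silencing factors 2 rose and 1 fell (3 and 1 adjusted over the list alone). Panx rose 1.59-fold (log2 0.67, SE 0.10, adjusted p = 0.000589), wde, named after its value was seen, rose by a log2 of 0.38, and the gene that fell was nxf2 itself. piRNA cluster transcription and export had 2 of 14 higher and 1 lower, and piRNA biogenesis and nuage 2 of 22 higher and 2 lower, both the same adjusted over the list alone. Across the 4 tested genes of the reproductive tract 2 fell, Ilp7 and the octopamine receptor gene Octbeta2R (log2 -1.38, SE 0.26), and of 22 genes of DNA damage and apoptosis 1 rose and 6 fell (1 and 7 adjusted over the list alone), with the apoptosis inducer rpr at -1.56.

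In all, 691 genes were higher and 665 lower in the knockdown by edgeR's quasi-likelihood test, 149 and 169 of them at least 2-fold. The split turned to 568 and 822 with upper-quartile scaling, 557 and 775 with no filter and 581 and 661 with a filter at 5 CPM. The count of 1356 was 546 without knockdown replicate 1, 2464 without attp2 replicate 1 and 188 in a fit of these 4 libraries alone, where Panx had an adjusted p of 0.0598, Syt4 0.0869, br 0.0852, CG43250 0.0697, Octbeta2R 0.0625 and rpr 0.0699. Against W1118 in place of attp2 the log2 fold change changed sign for CG6910 (1.74), ndl (-0.21), Eip74EF (-0.15) and rpr (1.78), and Tsf1 had no count in W1118. With that control the calls of Vm32E (log2 0.08, adjusted p = 0.494), Ilp7 (-0.78, 0.157) and Fas3 (0.20, 0.227) were also lost.

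The mutant and W1118 were compared to ask the same of a mutation of nxf2. Genes with no count in W1118 were expressed in the mutant. dys was at 69.8 ± 5.25 CPM (SD, n = 2), at least 241-fold higher than a floor of 3 counts over the W1118 group allows (adjusted p = 5.48e-09), CG1090 at 63.6 ± 9.17 CPM, at least 223-fold higher, and Syt4 at 59.6 ± 1.36 CPM, at least 206-fold higher. CG31202 was at 36.2 ± 2.2 CPM, at least 126-fold higher, and Gyc-89Da, which encodes a guanylate cyclase, at 14.1 ± 0.639 CPM, at least 48.8-fold higher. CG4970 was at 70.6 ± 37.6 CPM, at least 252-fold higher, with an adjusted p of 0.000196, and 0.165 in a fit of these 4 libraries alone. The Hox gene Dfd went the other way, from 70.7 ± 3.94 CPM to 2 counts in both mutant libraries together, a ratio of 594 (95% counting interval 164 to 4920), and CG4562 fell from 51.7 ± 2.89 to 4.2 ± 1.04 CPM.

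**Figure D2:**
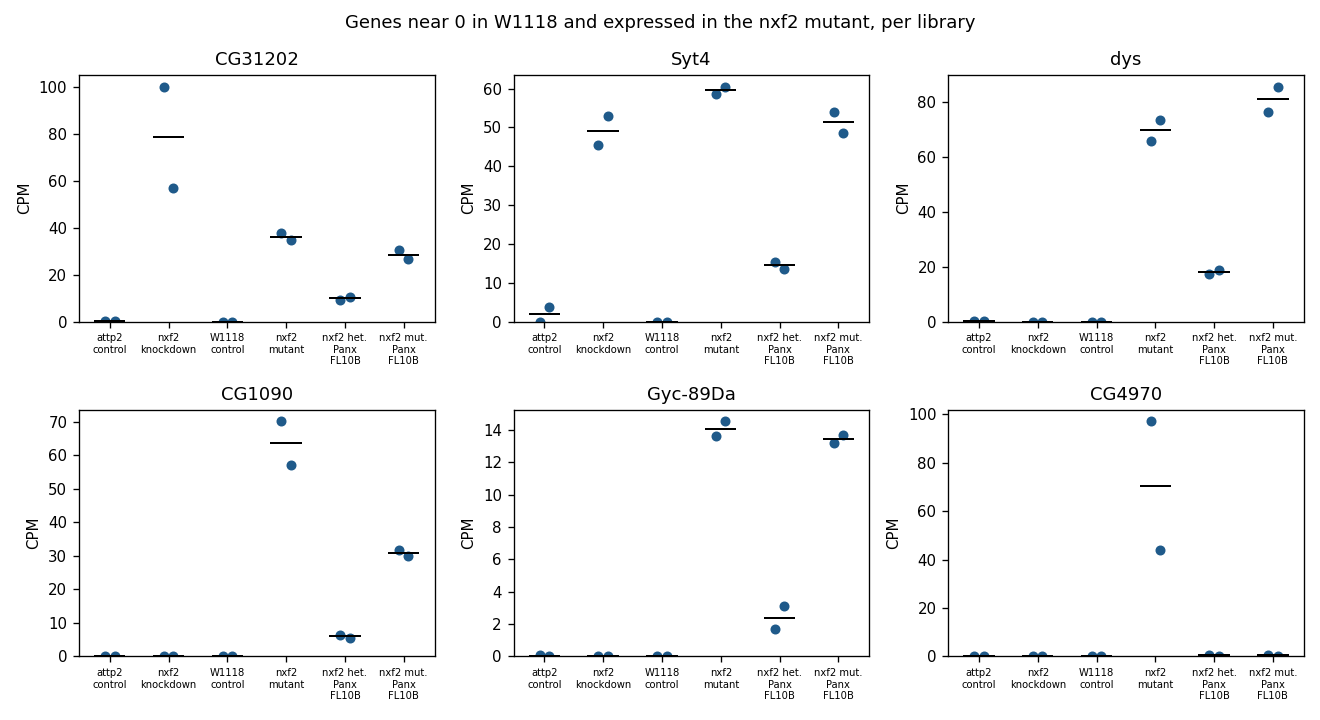
Normalised read count (CPM, linear axes from 0) of CG31202, Syt4, dys, CG1090, Gyc-89Da and CG4970 in each of the 12 libraries, by group, with a line at the mean of the 2 libraries. All 6 genes had 0 counts in W1118 and 14.1 to 70.6 CPM on average in the mutant, and CG31202 and Syt4 alone of them rose in the knockdown.

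Ribosomal protein genes rose in the mutant: 52 of 88 were higher and 3 lower (56 and 4 adjusted over the list alone), RpS23 from 972 ± 32.3 to 2259 ± 110 CPM (SD, n = 2) and RpL18 from 272.2 to 488.8 CPM. The list had a camera adjusted p of 1.75e-08, and adjusted p = 0.447 with an estimated correlation. Yolk and vitellogenesis genes fell, with 4 of 9 lower and none higher on both adjustments, Yp3, a yolk protein gene, from 436.5 ± 25.8 to 119 ± 18 CPM and ndl 1.73-fold (adjusted p = 0.0143, and adjusted p = 0.391 with an estimated correlation). Eggshell genes split, with 6 of 22 higher and 5 lower (8 and 5 adjusted over the list alone, list adjusted p = 0.992): 5 chorion genes rose, Cp38 by a log2 of 1.25 (SE 0.17), while 5 vitelline membrane genes fell. The mRNA of the posterior determinant osk fell from 1537 ± 38.5 to 894 ± 5.4 CPM and that of pgc rose 1.91-fold, within an oocyte and maternal list that had 4 of 22 higher and 5 lower on both adjustments.

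Some fat body, immune and hemocyte genes were higher in the mutant, while 3 of the 4 reproductive tract genes and 1 of 7 testis genes were lower. Of 18 muscle genes 1 was higher, and 0 adjusted over the list alone, a call lost in a fit of these 4 libraries (0.301) and without mutant replicate 1 (0.358) or W1118 replicate 1 (0.0957) or 2 (0.23). Of 9 fat body genes 3 rose (3 adjusted over the list alone). Tsf1 was at 2.94 ± 0.114 CPM (SD, n = 2) against no count, at least 10.2-fold higher. The list passed at 0.0143 but not without mutant replicate 1 (0.0604), and had an adjusted p = 0.391 with an estimated correlation. Of 8 antimicrobial and immune genes 4 rose (5 adjusted over the list alone), the peptide gene Dro from 0.668 ± 0.511 to 12.6 ± 8.98 CPM. That list passed at 0.0143 but not without mutant replicate 2 (0.0634), and had the same adjusted p = 0.391 with an estimated correlation. Hemocyte and basement membrane genes had 4 of 8 higher on both adjustments, the collagen gene vkg by a log2 of 1.06, with a list p of 0.048, and adjusted p = 0.429 with an estimated correlation. That call was lost with upper-quartile scaling (0.0515), without W1118 replicate 2 (0.235) and without mutant replicate 1 (0.122) or 2 (0.0634).

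Genes of the piRNA pathway changed in both directions in the mutant, where 26.8% of all tested genes were called. The counts below are to be read beside that share. Of 15 transcriptional silencing factors 4 fell on both adjustments, namely nxf2, Mi-2 (log2 -0.56, lost without mutant replicate 2 at 0.0533 or W1118 replicate 2 at 0.0715) and, named after their values were seen, Rpd3 (-0.37) and Su(var)3-3 (-0.34). The list did not pass (adjusted p = 0.0593, and adjusted p = 0.391 with an estimated correlation), but did without mutant replicate 2 (0.0412). In the same list Panx was at -0.20 (SE 0.11) and piwi at 0.10 (SE 0.31), neither of which passed. In piRNA cluster transcription and export 1 of 14 rose and 3 fell on both adjustments, with Ars2 at -0.67, and in biogenesis and nuage 3 of 22 rose and 1 fell (2 and 1 adjusted over the list alone). DNA damage and apoptosis had 5 of 22 higher and 5 lower (6 and 6 adjusted over the list alone), with Xrp1, a stress-response transcription factor gene, at 0.62 and tefu at -0.62. Octbeta2R (log2 -1.24, SE 0.28) was 1 of 3 of the 4 reproductive tract genes to fall, and aly, a testis gene, went from 7.08 ± 0.911 CPM (SD, n = 2) to 1 count, a ratio of 115 (95% counting interval 20 to 4610).

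The mutant had 1297 genes higher and 1021 lower than W1118, 506 and 153 of them at least 2-fold. This total of 2318 was 1009 without W1118 replicate 1, 821 without W1118 replicate 2 and 1258 without mutant replicate 1. Against attp2 in place of W1118 the sign changed for Ars2 (0.27), Cp38 (-0.97), ndl (0.37), aly (0.29), RpS23 (-0.08) and RpL18 (-0.52). With that control the calls of Dfd (log2 -0.56, adjusted p = 0.688), Tsf1 (0.04, 0.929), Xrp1 (0.01, 0.918), Dro (0.86, 0.0792), vkg (0.31, 0.0519), Mi-2 (-0.17, 0.302) and tefu (-0.21, 0.0752) were also lost.

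The mutant and the heterozygote that both carried Panx FL10B were compared to ask how the transcriptome differed between the genotypes in that background. Late eggshell genes were almost lost from the libraries labelled mutant. All 12 tested chorion genes fell, by 10.5- to 164-fold, with Cp38 at 8693 ± 52.6 CPM (SD, n = 2) in the heterozygote and 97.7 ± 0.935 CPM in the mutant (log2 -6.47, SE 0.21, adjusted p = 1.26e-10). The 9 vitelline membrane genes fell less, by 1.93- to 2.96-fold. Among the largest falls were also Muc4B, from 725.1 ± 22.7 to 3.79 ± 0.675 CPM and Muc12Ea, from 925.9 ± 69.9 to 5.33 ± 0.619 CPM. In total 21 of 22 eggshell genes fell (22 adjusted over the list alone), with a median log2 fold change of -4.20 and the exception of Cad99C at -0.40. The list's camera adjusted p was 1.02e-25, and its adjusted p = 0.0115 with an estimated correlation made it the 1 call of the 18 on lists in the 4 comparisons of groups that held there.

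**Figure D3:**
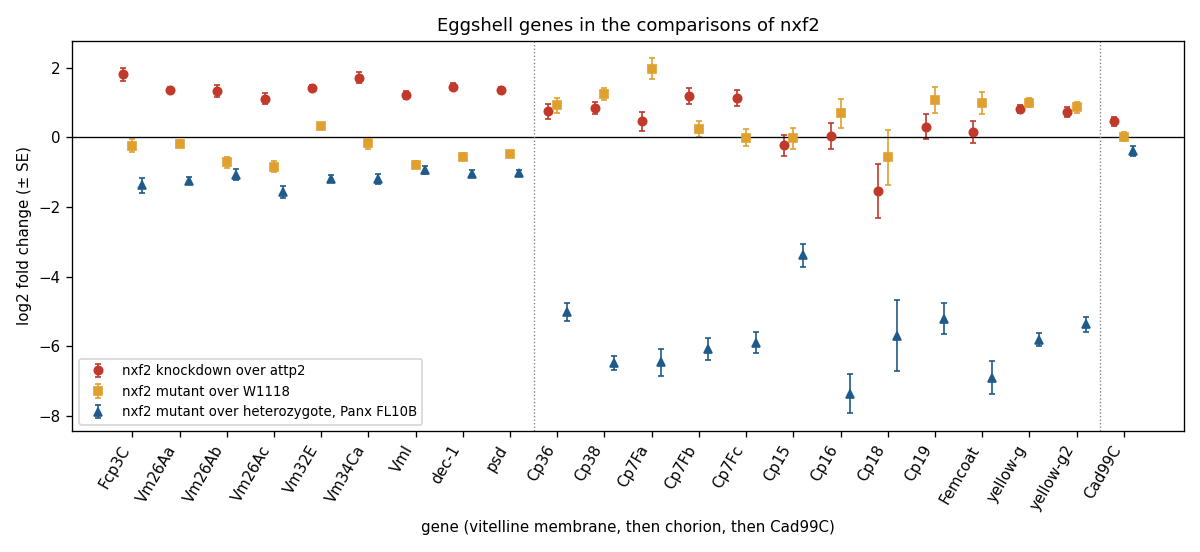
Log2 fold change of the 22 tested eggshell genes in the knockdown over attp2, the mutant over W1118 and the mutant over the heterozygote with Panx FL10B, with error bars of 1 SE. The order is vitelline membrane genes (a group by name that takes in dec-1 and Fcp3C), chorion genes and Cad99C. The chorion genes fell by -3.39 to -7.36 with Panx FL10B, where the vitelline membrane genes fell by -0.95 to -1.57.

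Xrp1, rpr and hid rose in the same mutant. Xrp1 went from 130 ± 13.7 to 368.6 ± 9.84 CPM (SD, n = 2) and rpr from 2.63 ± 0.239 to 15.2 ± 1.1 CPM, and W, the apoptosis gene hid, rose by a log2 of 1.33, in a list of 22 with 4 higher and 1 lower (5 and 2 adjusted over the list alone) that did not pass as a whole (adjusted p = 0.272). Genes silent in W1118 were higher again, dys from 18.2 ± 1.12 to 81.2 ± 6.47 CPM, CG1090 from 5.94 ± 0.697 to 30.8 ± 1.27 CPM and Gyc-89Da from 2.4 ± 0.982 to 13.4 ± 0.357 CPM. cngl rose from 24.2 ± 2.64 to 123.9 ± 5.02 CPM. Both Hsp27 (log2 -0.98) and Hsp26 (-0.81) fell, with 1 of 17 heat shock genes higher and 2 lower on both adjustments.

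Early germline genes were higher, 5 of 18 with 2 lower (8 and 2 adjusted over the list alone), mei-P26 by a log2 of 0.73 and A2bp1 by 0.59 (adjusted p = 0.0319, lost without mutant with Panx FL10B replicate 2 at 0.0641, and adjusted p = 0.275 with an estimated correlation). Oocyte and maternal genes had 6 of 22 higher and 3 lower on both adjustments, with osk up from 1066 ± 45.9 to 1670 ± 62.8 CPM (SD, n = 2) and orb 1.63-fold (list adjusted p = 0.272). In piRNA biogenesis and nuage 6 of 22 rose and 3 fell, also on both adjustments, where 19.5% of all tested genes were called. The rises were led by the Tudor genes qin (log2 0.90) and tud (0.67), with a list p of 0.111. Of the silencing factors 2 of 15 rose and 2 fell (2 and 3 adjusted over the list alone), the histone deacetylase gene Rpd3 from 237.7 ± 2.35 to 132.8 ± 3.8 CPM. In piRNA cluster transcription and export 3 of 14 rose (3, with 1 lower, adjusted over the list alone), with del at 0.46 (SE 0.10).

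Genes of several other lists moved both ways. Of 18 muscle genes 5 rose and 1 fell (8 and 1 adjusted over the list alone), with, named after their values were seen, sls at 1.36 and wupA at 0.93 (adjusted p = 0.0035, and adjusted p = 0.548 with an estimated correlation). Of 8 antimicrobial genes 3 fell (4 adjusted over the list alone), IM4 20.7-fold and Dro 25.0-fold, a list that passed at 0.0479 but not unscaled (0.0741), without heterozygote replicate 2 (0.442) or without mutant with Panx FL10B replicate 1 (0.107), with adjusted p = 0.548 with an estimated correlation. Yp3 fell 3.86-fold in a yolk list of 1 higher and 3 lower of 9 (2 and 4 adjusted over the list alone), and the GATA factor gene srp fell 3.92-fold in a hemocyte list of 1 higher and 1 lower of 8 on both adjustments. Oamb, an octopamine receptor gene, fell from 17.5 ± 2.77 to 0.978 ± 0.569 CPM (SD, n = 2) and Ilp7 24.5-fold, as 2 of the 3 of 4 reproductive tract genes that fell. Follicle cell patterning and ribosomal proteins also passed at 0.0319, with 1 of 17 higher and 1 lower and with 3 of 88 higher and 1 lower (1 and 0 adjusted over the list alone). They had adjusted p = 0.548 and 0.777 with an estimated correlation, the first was lost without mutant with Panx FL10B replicate 1 (0.0781), and the second without heterozygote replicate 1 (0.192).

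With Panx FL10B, 801 genes were higher and 885 lower in the mutant than in the heterozygote, 200 and 316 of them at least 2-fold. The split turned to 884 and 840 with RLE, 911 and 814 with upper-quartile scaling, 704 and 675 with DESeq2 and 864 and 703 with a filter at 5 CPM. The total of 1686 was 802 and 721 without heterozygote replicate 1 and 2, 763 without either replicate of the mutant, and 3690, split 1920 and 1770, in a fit of these 4 libraries alone.

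The 2 wild-type stocks were compared to give the size of a difference between stocks measured in the same way. W1118 differed from attp2 in 55.5% of the tested genes. The white gene w, which W1118 carries as a mutant allele, was at 28.5 ± 3.39 CPM (SD, n = 2) in attp2 with no count in W1118, at least 98.9-fold lower, and Dfd was at 0.184 ± 0.00169 CPM in attp2 and 70.7 ± 3.94 CPM in W1118 (log2 8.46, SE 0.40, adjusted p = 5.98e-09). Panx was 3.15-fold and piwi 4.53-fold lower in W1118, the HP1a gene fell from 1540 ± 4.91 to 412.4 ± 24.9 CPM, and nxf2 was 1.62-fold higher. Replication histones were lower for 19 of 21 and higher for 1 on both adjustments, His4:CG33891 at least 31.8-fold (list adjusted p = 1.75e-11, and adjusted p = 0.281 with an estimated correlation). Copies of His1 and of His4 had near-equal values, so these counts may hold 1 measurement more than once. Ribosomal protein genes were lower for 61 of 88 and higher for 9 (61 and 10 adjusted over the list alone), with RpS7 from 4670 ± 368 to 924.6 ± 22.9 CPM (adjusted p = 1.87e-07, and adjusted p = 0.961 with an estimated correlation). Of the vitelline membrane genes 7 of 9 were higher and of the chorion genes 2 of 12 higher and 9 lower. Among genes of smaller lists, testis and male germline had 1 of 7 higher and 1 lower, nuclear RNA export factors 4 of 11 each way, transgene markers 1 of 3 each way (1 and 2 adjusted over the list alone), and midgut enzymes 1 of 2 lower (2 adjusted over the list alone). W1118 was higher for 2175 genes and lower for 2616, a total of 4791 that ranged from 3464 to 4851 when single libraries were left out.

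Whether the knockdown and the mutant had different effects was tested as a difference of the 2 log2 fold changes, each against its own stock. Eggshell genes stood 0.68 (median log2) higher in the knockdown effect, with 10 of 22 higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.000221), and ribosomal protein genes 0.60 lower, with 53 of 88 lower and 2 higher (64 and 2 adjusted over the list alone, adjusted p = 2.22e-10). Both had an adjusted p = 0.349 with an estimated correlation. dys, Gyc-89Da and CG1090 had 14.1 to 69.8 CPM in the mutant and at most 0.115 CPM in the knockdown, with adjusted p of 0.000914, 0.0158 and 0.00588 for the difference. The last 2 calls were lost without attp2 replicate 1 (adjusted p = 1), and attp2 replicate 2 had no count of either gene. CG42255 rose in the knockdown from 0.924 ± 0.399 to 29.3 ± 12.4 CPM (SD, n = 2) and went from 4.1 ± 1.47 to 0.381 ± 0.38 CPM in the mutant (difference 8.35, SE 0.76, adjusted p = 1.76e-05). In all, 2331 genes differed, and 1411 without W1118 replicate 1, 1252 without W1118 replicate 2 and 1522 in a fit of these 8 libraries alone.

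The number of genes higher in both was close to that of independent lists. The comparisons shared 108 higher genes where independent lists give 104 (one-sided Fisher exact p = 0.335) and 88 lower genes against 78.6 (p = 0.134, adjusted over the 6 overlaps tested 0.161), while 202 genes were higher in the knockdown and lower in the mutant, against 81.7, and 112 the other way, against 99.9. Pearson's r of the 2 sets of log2 fold changes was 0.05 across genes, which are not independent replicates. CG31202 and Syt4 were among the genes that rose in both, and Octbeta2R and Ilp7 among those that fell in both, the last without its mutant call when mutant replicate 1 (0.0849) or W1118 replicate 2 (0.0545) was left out. The 196 genes of both directions were 96 without W1118 replicate 1, 92 without W1118 replicate 2 and 57 in fits of each comparison's own libraries.

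Whether the effect of the mutation differed with Panx FL10B was tested in the same way, with a heterozygote as control on one side and a wild-type stock on the other. The eggshell list did not pass without Panx FL10B (adjusted p = 0.992). Its genes had a lower effect with it, 19 of 22 with none the other way on both adjustments and a median difference of -4.24 (camera adjusted p = 2.24e-15, and adjusted p = 0.0448 with an estimated correlation). Antimicrobial genes had 5 of 8 lower on both adjustments (adjusted p = 0.00597, and adjusted p = 0.391 with an estimated correlation). Ribosomal proteins had 19 of 88 lower and 2 higher (19 and 4 adjusted over the list alone, adjusted p = 0.00782, and adjusted p = 0.575 with an estimated correlation), which was lost without heterozygote replicate 2 (0.0601) or mutant replicate 2 (0.116). dys rose in both, with a smaller effect with Panx FL10B (adjusted p = 5.83e-07), at 18.2 ± 1.12 CPM (SD, n = 2) in the heterozygote and no count in W1118. Cyp6d2, a cytochrome P450 gene, went from 6.57 ± 2.36 to 0.801 ± 0.765 CPM without and from 3.98 ± 0.819 to 19.7 ± 2.55 CPM with Panx FL10B (difference 5.19, SE 0.63, adjusted p = 8.28e-05).

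More genes moved the same way with and without Panx FL10B than independent lists give, 154 higher against 120 (one-sided Fisher exact p = 0.000396, adjusted 0.000594) and 159 lower against 105 (p = 9.86e-09, adjusted 1.97e-08), with r = 0.08 across genes. Genes that moved opposite ways were in excess too, 165 higher without and lower with Panx FL10B against 133, and 109 the other way against 94.7, which were not tested. Lists drawn within deciles of expression were not tried for this pair. With an excess in both directions, the Fisher tests against independent lists cannot show that the direction was shared. dys, CG1090 and Gyc-89Da were among those higher in both, and Yp3, ndl and Octbeta2R among those lower. A difference of effect was called for 1833 genes, which became 1189 and 993 without W1118 replicate 1 and 2. It became 1065 without heterozygote replicate 2, 1182 and 1138 without mutant with Panx FL10B replicate 1 and 2, and 3160 in a fit of these 8 libraries alone. The 313 shared genes were 157 without mutant replicate 1, 146 and 139 without W1118 replicate 1 and 2, and 144 and 135 without heterozygote replicate 1 and 2. They were 148 and 140 without mutant with Panx FL10B replicate 1 and 2, and 817 in fits of each comparison's own libraries.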

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

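The tests of fewer late egg chambers and all 4 tests on the genes silent in W1118 were chosen only after the result was seen, while those of scaling and of library preparation were written down beforehand.

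The knockdown and the mutant differed in their effect, each against its own stock, for 2331 genes. Adjusted p for the difference was 0.00269 for Dfd, at 70.7 CPM in W1118 and at most 0.467 CPM in every other group, and 0.977 without knockdown replicate 2. It was 1.76e-05 for CG42255, 1.38e-06 for CG4562 and 0.000294 for mthl8, all higher in the knockdown effect. It was 0.000914 for dys, 0.00154 for CG9766, 0.0158 for Gyc-89Da and 0.00588 for CG1090, all lower in the knockdown effect. The calls of Gyc-89Da and CG1090 were lost without attp2 replicate 1, with fitted differences of -9.72 and -8.9. The attp2 library that was left had no count of either gene, so that setting cannot test them. Exchanging the stocks as controls cannot test these 4 genes, since dys, CG9766 and Gyc-89Da had no count in the knockdown or W1118, and CG1090 stood at 0.115 CPM in the knockdown with no count in W1118. Among gene lists the effects differed for chorion and vitelline membrane (camera adjusted p = 0.000221), yolk (0.0146), antimicrobial and immune genes (0.0147), fat body (0.00355), ribosomal proteins (2.22e-10) and replication histones (0.000221), all at adjusted p = 0.349 with an estimated correlation.

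The effect of the mutation with Panx FL10B differed from that without it for 1833 genes. Adjusted p was 9.29e-05 for Dfd, 8.28e-05 for Cyp6d2, 0.00368 for CG12708, 0.00027 for Cyp9b2 and 5.83e-07 for dys, and with attp2 as control the call of Dfd was lost (0.194). CG13532 passed at 0.023, but not without heterozygote replicate 1 (0.0739) or 2 (0.0814) or without mutant with Panx FL10B replicate 1 (0.191) or 2 (0.072), nor with attp2 as control (0.0573). CG4970 passed at 0.0298, but not without W1118 replicate 2 (0.0602) or heterozygote replicate 1 (0.177) or 2 (0.115), nor in a fit of the 8 libraries alone (0.231). Syt4 passed at 0.0198, but not without W1118 replicate 1 (0.0503) or 2 (0.0909), heterozygote replicate 1 (0.0586) or 2 (0.0619), or mutant with Panx FL10B replicate 1 (0.0606) or 2 (0.0639). Of gene lists, chorion and vitelline membrane differed at 2.24e-15 (adjusted p = 0.0448 with an estimated correlation), antimicrobial and immune genes at 0.00597 (0.391) and ribosomal proteins at 0.00782 (0.575), the last not without heterozygote replicate 2 (0.0601) or mutant replicate 2 (0.116).

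Eggshell genes were far lower in the mutant than in the heterozygote with Panx FL10B. Scaling of the libraries is argued against, since the median log2 fold change of the 22 genes was at most -4.17 under 4 other scalings. Fewer late egg chambers in these ovaries may account for it: chorion genes, which follicle cells express last, had a median 4.67 lower than vitelline membrane genes, which they express earlier (difference -4.67), and the oocyte and maternal list did not fall. Whether fewer such chambers came from the mutation, from the stock or from the age of the flies was not tested.

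Genes silent in W1118 were expressed in the mutant, with 27 at 3 or fewer pooled counts in W1118 and at least 5 CPM in both mutant libraries against 4 the other way (two-sided exact binomial p = 3.4e-05). A difference between stocks apart from the nxf2 mutation cannot be told apart from the mutation: 15 of the 27 (55.6%, exact interval 35.3 to 74.5) rose again in the mutant over the heterozygote with Panx FL10B, against 9.13% of other genes, but the labels do not say that these groups share a stock, and nxf2 RNA did not separate them (adjusted p = 0.334). Alleles linked to nxf2 on chromosome 3 cannot be told apart from it either, since 9 of the 14 placed genes that rose in both lay on 3L or 3R (64.3%, exact interval 35.1 to 87.2, around the 43.2% of all tested genes) and a linked allele can act on genes of other arms. Stock differences in on against off calls cannot be told apart from the mutation. W1118 against attp2 was uneven too, with 2 genes on and 18 off (exact binomial p = 0.000402). Copies of His1 and His4 with near-equal values, whose reads may be shared, are among the 18. That p therefore counts the same signal more than once and cannot say how uneven the stocks were. W1118, which had more silent genes in each of these comparisons, had total counts of 3811630 and 6467850. The mutant had 8817078 and 7661682, and attp2 11100934 and 11260925. A cutoff of 3 pooled counts was therefore easier to meet in W1118, which the binomial tests do not take into account. Loss of nxf2 stays open, with 18.5% of the 27 (5, exact interval 6.3 to 38.1) rising in the knockdown against 7.97% of other genes (one-sided Fisher exact p = 0.0599), and 7 of the 27 stood under 0.5 CPM in both Panx FL10B groups, CG4970, CG31760, CG15483, CG13872, CG12672, CG7329 and CG6867, named after their values were seen.

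The attp2 and knockdown libraries stood apart from the other 8, with 203 genes at least 2-fold above or below all of them, against 42 for W1118 and mutant and 153 for the Panx FL10B libraries, sets defined from the data. Library preparation cannot be told apart from stock. The SD over ribosomal protein genes of log2 W1118 over attp2 was 1.28 times that of the heterozygote with Panx FL10B over W1118. Its 95% bootstrap interval, 0.919 to 2.32, lay on both sides of the bound of 1.5. The bootstrap took these correlated genes (estimated correlation 0.357) as independent. The second contrast also joins libraries whose processing notes differ and may hold a preparation difference itself, so the ratio cannot decide. A difference in genotype between the stocks remains an untested alternative.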

How the results depend on the processing

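Every setting named here was planned except the one without small RNA and multi-copy genes, which was chosen only after the result was seen and left the 6 counts of called genes within 1.5 times. RLE, upper-quartile scaling, DESeq2, no filter and a filter at 5 CPM left all 8 counts of genes within 1.5 times too. The cause was not tested of any change below, except that requiring 2-fold or leaving out a library removes calls or samples by construction.

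Requiring at least 2-fold left 318 genes in the knockdown, 659 in the mutant, 516 with Panx FL10B and 1711 between stocks, 829 and 781 for the differences of effect, and 60 and 97 of the shared genes. In a fit of the compared groups alone the counts were 188 for the knockdown, 3690 with Panx FL10B, 1522 and 3160 for the differences, and 57 and 817 for the shared genes. The other wild-type stock as control gave 4485 for the knockdown, 4849 for the mutant, and 5476 and 3336 for the differences. The mean of both stocks gave 2937, 3620, 4816 for the difference of knockdown and mutant, and 396 for the genes they share.

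Leaving out each library in turn gave 546 to 2464 genes for the knockdown, 821 to 1707 for the mutant, 721 to 802 with Panx FL10B and 3464 to 4851 between stocks. The differences of effect ranged from 1252 to 3268 and from 993 to 1561, and the shared genes from 92 to 290 and from 135 to 309. The lone library of a group was taken to vary like the other groups. Called lists ranged from 3 to 8, 3 to 5, 4 to 6 and 2 to 2. With an estimated correlation, 0 lists were called for the knockdown, 0 for the mutant, 1 with Panx FL10B and 0 between stocks. Of the 19 lists camera with its preset correlation called 5, 5, 6 and 2, and fry called 4, 9, 9 and 8. With a filter at 5 CPM camera called 4 lists in the knockdown (3 higher and 1 lower) and 3 in the mutant (1 higher and 2 lower). It called 3 with Panx FL10B and 1 between stocks. Without that filter the knockdown had 2 higher and 3 lower and the mutant 4 higher and 1 lower, so the lists called were not all the same.

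The same replicate numbers share no stated origin, and deviations of same-numbered libraries from their group means correlated at 0.077, -0.022 and -0.055 in the 3 comparisons of nxf2, so the numbers do not pair the libraries. With the replicate block 1314, 2312, 1661 and 4758 genes were called in the 4 comparisons, 2327 and 1835 for the differences, 183 and 303 as shared, and 4, 5, 5 and 2 lists.

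Log2 fold changes reversed mainly with the other stock as control. In the knockdown this gave piwi 1.95 (0.864 with the mean of both stocks), CG4716 0.368, CG13321 0.556, CG6910 1.74, CG13741 -0.258, ndl -0.213, Eip74EF -0.15, rpr 1.78 (mean 0.11), IM3 0.397, twe 0.398, Tsf1 3.95 (mean 0.21), RpS26 0.79 (mean 0.126), and His4:CG33891 and His4:CG33893 8.07 each (mean 3.49 each). Tsf1 and both His4 genes had no count in W1118, so these are fitted values that depend on the prior count and give no fold. In the mutant it gave piwi -2.08 (mean -0.992), Ars2 0.273, zuc -0.146, stil -0.507, mtrm -0.471 (mean -0.0621), Cp38 -0.973, ndl 0.372, ct 0.00405, stv -0.764 (mean -0.0261), aly 0.29, w -6.03 (mean -0.638), RpS23 -0.0841 and RpL18 -0.521. For the difference of knockdown and mutant Dfd went to -7.98. Over 238 pairs of a named gene and a comparison, with their settings, 2991 values kept their side of the threshold. Another 307 fell short of it, 5 newly passed it and 38 reversed. A change of sign was counted as a reversal only where the main or the alternative value passed, so some of the 2991 may have changed sign. Of the calls of named genes, leaving out 1 library ended 20 of 49 in the knockdown, 16 of 52 in the mutant, 11 of 51 with Panx FL10B and 4 of 60 between stocks. In fits of the compared groups alone, 30 of the 49 calls were lost in the knockdown, 4 of the 52 in the mutant, 0 with Panx FL10B and 0 between stocks. Depth limits genes near 3 counts, at 0.275 to 0.772 CPM per library.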

Other observations

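The tests in this part were chosen only after the result was seen, apart from the 3 unmatched ones for nearby annotated transposons and the count of 108 genes shared at any fold, which were planned.

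Some genes changed the same way wherever nxf2 was reduced or mutated. In the knockdown, the mutant and the mutant with Panx FL10B, 31 genes were higher and 27 lower each time, where independent lists give 9.62 and 8.05. Independent lists take no account of genes that are called more readily in every comparison. Genes called each time with mixed directions were not counted, so this excess alone cannot show a shared response. CG31202 rose by log2 8.61 (SE 0.41), at least 126-fold and by 1.53 (SE 0.26), and Jheh3, a juvenile hormone epoxide hydrolase gene, by 1.13, 1.41 and 1.41. The P450 gene Cyp12a4 rose by 2.88, 3.62 and 1.92 and the adhesion gene Dscam2 by 4.07, 2.36 and 2.25. Ilp7 fell by -2.94, -2.22 and -4.61, Ilp8, another insulin-like peptide gene, by -2.24, -0.78 and -4.76, Octbeta2R by -1.38, -1.24 and -1.68, and the acetylcholine receptor gene nAcRalpha-80B by -1.76, -1.61 and -0.95. The apoptosis gene hid (W) rose by 0.85, 1.04 and 1.33. The genes named in this part were chosen after their values were seen. The mutant call of Ilp7 was lost without mutant replicate 1 (0.0849) or W1118 replicate 2 (0.0545), its knockdown call with W1118 as control (0.157), and the knockdown call of Octbeta2R in a fit of those 4 libraries alone (0.0625). The knockdown and the mutant with Panx FL10B shared 140 higher genes against 64.1 for independent lists and 155 lower genes against 68.1 (one-sided Fisher exact adjusted p = 5.25e-20 and 5.61e-24). They also held 106 genes higher in the knockdown and lower in the mutant with Panx FL10B, against 70.8, and 26 the other way, against 61.7, and Pearson's r of their log2 fold changes across genes was 0.07.

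Genes of chromosome 4 were called as a set in 3 comparisons by camera with its preset correlation and in none with an estimated correlation. Of its 72 tested genes 3 rose and 15 fell in the knockdown (camera adjusted p = 0.000576), 21 rose and 2 fell in the mutant with Panx FL10B (1.34e-05), and 41 were higher and 5 lower in W1118 than in attp2 (3.2e-05). In the mutant 5 rose and 17 fell (0.849). With an estimated correlation the adjusted p were 0.662, 0.905, 0.88 and 0.841, and by that test no arm passed in any of the 4 comparisons.

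Genes that rise without nxf2 may lie near transposons, whose silencing the piRNA pathway directs. Of genes at least 4-fold higher, the odds of an annotated transposon inside or within 5 kb were 1.98 times those of other genes in the knockdown (95% interval 1.01 to 3.77), 1.67 times in the mutant (1.25 to 2.22) and 1.44 times with Panx FL10B (0.838 to 2.42). Among 10000 random sets matched for gene span and expression, shares of 0.133, 0.0203 and 0.39 had as many such genes, or 0.266, 0.122 and 0.585 after adjustment over 6 sets. For genes at least 4-fold lower these shares were 0.0769 in the knockdown (31.6% against a median of 22.8%), 0.57 in the mutant (27.6% against 27.6%) and 0.683 with Panx FL10B. None of these passed after adjustment, and genes that rose and genes that fell were not tested against each other. Of the genes that rose 38.6%, 34.5% and 31.5% had such a transposon, against matched medians of 29.5%, 28.4% and 28.8%. The mutant's value lay just above the middle 95% of its matched sets (22.8% to 34.1%). Since none passed after adjustment, the excess cannot be told apart from that of genes of like span and expression. The reference genome also does not show the transposons of these stocks.

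Although the knockdown and the mutant shared about as many higher genes (108) as independent lists give (104), genes with large changes in both may be a common set. At 4-fold or more they shared 14 genes, among them Syt4, CG31202, ppk13 and Rootletin, where independent lists give 1.24 and lists drawn within deciles of expression 3.86 (adjusted p = 4e-04 over 8 folds and directions, from 1e-04, the smallest that 10000 draws can give). At 2-fold they shared 30 higher against 15.7 within deciles and 30 lower against 6.41, at 4-fold 7 lower against 1.36, and at 8-fold 8 higher against 1.32 and 1 lower against 0.207, of which the last did not pass. At any fold they shared 88 lower genes against 70.8 within deciles (adjusted p = 0.013). Opposite movement was in excess as well. At any fold 202 genes were higher in the knockdown and lower in the mutant against 111 within deciles, and 112 the other way against 102. Of genes lower in the knockdown 27 were as much higher in the mutant at 2-fold against 20.4, 10 at 4-fold against 5.33 and 4 at 8-fold against 1.2. For genes higher in the knockdown 6 were opposite at 2-fold against 4.89, 1 at 4-fold against 0.981 and 1 at 8-fold against 0.233, and none of these opposite counts was tested. Some of the 14 genes shared at 4-fold lay near the floor. With no count in W1118, danr stood at 0.604 CPM and CG13168 at 1.31 CPM in the mutant, so their fitted folds there depend on the prior count.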
